A study of Mus musculus with 70 samples.

How the data were processed

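RNA-seq of 54 libraries was used, from mouse ES cells (day 0) and neural progenitor cultures (days 8 and 14) of 6 genotypes, with 3 libraries per genotype and day. Per the labels, cells were lysed in ISOGEN, total RNA was purified with PureLink columns, and the reads were handled with Trimmomatic, HISAT2 2.2.0 and featureCounts against the mouse genome mm10. Bowtie2 2.4.5, Picard, deepTools 3.5.1 and MACS2 are named too, and which tool served which assay is not stated. Neither are the gene annotation, the gene lengths, the strand setting or any filter. The values are TPM as deposited by the authors, 1 column per library for 55401 genes, and each column sums to 1000000. TPM holds no read counts, so the depth per library and the counting error behind a value are unknown, and no counting interval or detection floor was computed. The 16 ChIP-seq samples in the labels, 4 of them inputs, were not analysed here.

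Genotype and day of each column were read from its heading. The columns headed KO were taken as CHD8+/- by elimination, since the labels name no other genotype that could be meant. The columns carry no replicate numbers, so a, b and c follow the order of the columns within a group, were paired with nothing between days or genotypes, and no replicate block was fitted. Of the genes, 9443 were listed at 0 in all libraries. The lowest Pearson r across genes between 2 libraries of a group was 0.983 at day 0, 0.883 at day 8 and 0.701 at day 14. Chromosome, start and end came from the RefSeq annotation of the mm10 build, matched by symbol or by a synonym that names 1 gene only, for 38559 genes.

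Values were analysed as log2(TPM + 1) with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend) in R 4.3.3, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Genes with a mean of at least 1 TPM over the libraries of a fit were tested: 15958 at day 0, 19408 at day 8 and 21209 at day 14. Each day had 1 fit of its 18 libraries, from which each mutant genotype was compared with WT (15 comparisons) and each missense genotype with CHD8+/- (12). The 9 WT libraries had a fit for day 8 against day 0 and day 14 against day 8, and all 54 libraries a fit for the change of each genotype's effect between days 0 and 14 (5), which makes 34 comparisons.

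Before the data were examined, 47 gene lists were written down, with the comparisons, the threshold, the alternatives and the rule for naming genes. Lists with at least 4 tested members were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation. The p-values were adjusted over 665 tests against WT and, apart from these, over 92 tests between WT days. Chromosomes with at least 50 tested genes were tested with camera and an estimated correlation (300 tests). Fold changes of missense genotypes and CHD8+/- were correlated across genes and set beside 100 simulations of unchanged groups sharing the WT libraries.

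Genes were named by rule. Chd8 was always named. For each comparison the rule takes genes past the threshold whose 3 libraries all lie above or all below the other 3, which chance gives for 10% of genes, and leaves out unnamed models, Riken clones and pseudogenes. Of these it names the 5 largest rises and falls against WT, the 2 largest against CHD8+/-, and the 8 largest between WT days. It adds the 2 largest changes each way for the change of effect, the genes past the threshold in the same direction in at least 4 genotypes of a day (at most 8 each way), and the 2 to 4 members with the largest change in each list described. Genes of the pluripotency, neural progenitor, neuron, p53 target and Wnt target lists can be named anywhere, and a gene named outside the rule is said to be so. Not every gene that the rule takes is named in the text.

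The alternatives were a pseudocount of 0.1 TPM, no filter on low values, median-of-ratios scaling of the libraries, the spread of the compared groups alone, an estimated correlation for lists, a mean of at least 5 TPM for chromosomes, and leaving out each library in turn. Leaving out CHD8+/- b of each day, and chromosome 8 from the L1072F/+ counts, were added after the data were seen. The fits were tested on simulated data with known changes. For L834P/+ against WT, 61.2%, 20.9% and 13.4% of 1.5-fold changes and 93.9%, 90.9% and 77.3% of 4-fold changes were called at days 0, 8 and 14. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.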

Results

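RNA was sequenced from mouse embryonic stem (ES) cells at day 0 and from neural progenitor cultures at days 8 and 14 of differentiation. Chd8 encodes a chromatin remodeller of the CHD family, and the series asks how missense mutations of it relate to autism spectrum disorder. Cells of 6 genotypes were compared: wild type (WT), a heterozygous Chd8 mutant called CHD8+/-, and 4 heterozygous missense genotypes, L834P/+, R910Q/+, L1072F/+ and R1242Q/+. Each genotype had 3 libraries at each of 3 days, which gave 54 libraries in 18 groups, and the libraries of a group are named a, b and c here by their order alone. Between 15824 and 16194 genes reached 1 TPM per library at day 0, 18703 to 19624 at day 8 and 19389 to 21494 at day 14. The read depth is unknown, since TPM keeps no counts. Levels below are mean TPM ± SD with n = 3 libraries per group, and fold changes are log2 fold changes of TPM + 1 ± SE from limma; a list's median is of the log2 fold changes of its members. Where a call ended without a library or under another setting, the adjusted p there stands in brackets. Nothing in the labels says that the libraries of a group came from separate cultures, so every p-value measures the spread between these libraries only, and that spread can be technical, although libraries of most mutant groups also differed in whole chromosomes (below).

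The day 8 and day 0 WT cells were compared to describe the differentiation on which the mutants were tested. Pluripotency genes fell from day 0 to day 8. Pou5f1, the core pluripotency transcription factor, went from 771 ± 23.9 TPM to 26.3 ± 3.53 TPM (log2 fold change -4.83 ± 0.20, adjusted p = 4.33e-08). Tdgf1, a Nodal co-receptor, fell by 6.04 and Tfcp2l1, a naive pluripotency factor, fell by 5.12 on the log2 scale. Of the pluripotency list, 0 of 24 rose and 24 fell, over all genes and adjusted over the list alone (median -3.79, camera adjusted p = 5.88e-18, 0.451 with an estimated correlation). The largest falls were of Trh (-7.57 ± 0.22, adjusted p = 5.22e-09), Tdgf1, Tdh, which encodes threonine dehydrogenase (-5.98 ± 0.19, adjusted p = 7.68e-09), and Lefty2, a Nodal inhibitor (-5.76 ± 0.19, adjusted p = 9.57e-09). Laptm5 (-5.58), Fgf4 (-5.55) and Pla2g1b (-5.29) fell too.

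Genes of the retinoic acid response and of the Hox clusters, the transcription factors of axial identity, rose from day 0 to day 8. Cyp26b1 and Cyp26a1, which degrade retinoic acid, were the first and the third by size, at 346 ± 44.4 TPM and 263 ± 33.2 TPM (log2 fold changes 7.87 ± 0.12 and 7.63 ± 0.15). Crabp2 and Crabp1, which bind retinoic acid in the cell, rose by 6.74 and 6.57. Of the retinoic acid list, 14 of 15 rose and 1 fell, over all genes and adjusted over the list alone (median 4.77, camera adjusted p = 0.000218, 0.214 with an estimated correlation). Of the Hox list, 27 of 29 rose and 2 fell, over all genes and adjusted over the list alone (median 5.51, camera adjusted p = 2.01e-06, 0.454 with an estimated correlation). Hoxa5 rose by 7.25 and Hoxb8 by 7.13. The other largest rises were of Igf2, a growth factor (7.83 ± 0.25, adjusted p = 9.43e-09), of Dbx1, a neural progenitor transcription factor (7.03 ± 0.27, adjusted p = 2.22e-08), and of Hoxb5os and Hoxb3os, which are named as antisense to Hox genes (7.51 ± 0.15 and 7.02 ± 0.08). Neural progenitor genes rose as well, led by Hes5, an effector of Notch (5.82 ± 0.11, adjusted p = 6.49e-10), Pou3f2 (5.22 ± 0.16) and Sox3 (5.03 ± 0.20). Of that list, 21 of 23 rose and 2 fell, over all genes and adjusted over the list alone (median 3.60, camera adjusted p = 0.000218, 0.614 with an estimated correlation). Of the neuron list, 25 of 31 rose and 2 fell, over all genes and adjusted over the list alone (median 2.28, camera adjusted p = 0.00748, 0.757 with an estimated correlation). Nhlh2 and Dcx led it (4.27 ± 0.17 and 4.17 ± 0.14).

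In total 11725 of 20375 genes rose and 4132 fell between these days in WT cells. With median-of-ratios scaling the median of all genes moved from 0.46 to 0.20, and 9439 genes rose and 6215 fell, so that changes of this comparison are stated relative to TPM totals. The calls named here held without each of the 6 libraries in turn.

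Between days 8 and 14, neuronal genes rose in WT cells. Slc17a6, the vesicular glutamate transporter, went from 0.144 ± 0.0664 TPM to 47.1 ± 6.10 TPM (5.39 ± 0.11, adjusted p = 2.2e-09), and Neurod6 rose by 5.14. Syt4 and Scg2, of secretory vesicles, rose by 5.76 and 5.57. Mapt, which encodes tau, and Gpm6a, a neuronal membrane protein, reached 366 ± 39.9 TPM and 314 ± 25.6 TPM. Of the neuron list, 21 of 31 rose and 3 fell, over all genes and adjusted over the list alone (median 2.90, camera adjusted p = 0.000476, 0.749 with an estimated correlation). Of the neuronal genes repressed by REST, 26 of 29 rose and 1 fell, over all genes and adjusted over the list alone (median 3.06, camera adjusted p = 6.19e-08, 0.481 with an estimated correlation). Of the neural progenitor list, 3 of 23 rose and 18 fell over all genes, 3 and 19 adjusted over the list alone (median -0.90, camera adjusted p = 1.85e-05, 0.545 with an estimated correlation). Fabp7, of radial glia, rose by 4.14, while Sox3 and Pax6 fell by 4.02 and 2.57.

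Markers of other cell types rose at the same time. Of the largest rises in WT cells to day 14, 4 were of placental genes, Prl2b1 (6.46 ± 0.10, adjusted p = 1.71e-09), Ctsj (6.40 ± 0.10), Tpbpa (6.18 ± 0.12) and Prl3b1 (6.17 ± 0.13). The matrix genes Dcn and Col1a1 rose by 5.12 and 4.01. Of the fibroblast list, 12 of 13 rose and 0 fell, over all genes and adjusted over the list alone (median 2.59, camera adjusted p = 0.00141, 0.637 with an estimated correlation). Mab21l2 rose by 6.63 and Tmem130 by 6.07. Genes of cell division and of the ribosome fell. Cenpf and Top2a, of mitosis, fell by 1.94 and 1.91. Of the G2/M list, 0 of 24 rose and 24 fell, over all genes and adjusted over the list alone (median -1.55, camera adjusted p = 1.83e-12, 0.545 with an estimated correlation). Of the cytosolic ribosomal proteins, 0 of 55 rose and 55 fell, over all genes and adjusted over the list alone (median -0.86, camera adjusted p = 3.23e-21, 0.467 with an estimated correlation), with Rps2 at -1.57 and Rpl12 at -1.24.

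The largest falls between days 8 and 14 were of Cyp26a1 (-5.68 ± 0.15, adjusted p = 6.85e-09), Dbx1 (-4.78 ± 0.27), Nepn (-4.68 ± 0.20), Igdcc3 (-4.60 ± 0.11), Hk3 (-4.60 ± 0.09), Ripply3 (-4.48 ± 0.14) and the proneural factor Neurog1 (-4.24 ± 0.22). Foxe3, at 18.3 ± 0.970 TPM at day 8, was listed at 0 in the day 14 WT libraries, so it has no fold. In total 8919 of 20375 genes rose and 5423 fell, and the named calls held without each of the 6 libraries in turn.

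The level of Chd8 RNA itself was compared next (ENSMUSG00000053754, mm10 chromosome 14, 52198151 to 52258042). CHD8+/- cells at day 0 held 15.9 ± 1.72 TPM against 24.1 ± 0.665 TPM in WT cells, and this fall passed the test (-0.58 ± 0.07, adjusted p = 0.00330; 0.409 with the spread of the compared groups alone). At day 8 they held 19.8 ± 4.19 TPM against 29.5 ± 1.10 TPM (-0.57 ± 0.13, adjusted p = 0.148), and at day 14 23.9 ± 8.19 TPM against 36.6 ± 1.83 TPM (-0.65 ± 0.18, adjusted p = 0.236; -0.37 without CHD8+/- b). Neither passed. L1072F/+ cells held 20.7 ± 0.506 TPM at day 0 (-0.21 ± 0.07, adjusted p = 0.0568; 0.0175 with the spread of the compared groups alone and 0.0316 without CHD8+/- b in any fit). Chd8 fell in them at day 8, to 20.5 ± 0.630 TPM (-0.51 ± 0.13, adjusted p = 0.00536), and at day 14, to 25.3 ± 0.960 TPM (-0.52 ± 0.18, adjusted p = 0.0459). The day 8 fall in CHD8+/- cells passed without CHD8+/- a (-0.70, adjusted p = 0.0301). The day 14 fall in L1072F/+ cells did not pass without WT a (0.105), WT b (0.0745), WT c (0.127), L1072F/+ a (0.0934), L1072F/+ b (0.117) and L1072F/+ c (0.0961), nor with median-of-ratios scaling (-0.29, adjusted p = 0.111), a pseudocount of 0.1 TPM (0.0508) or no filter on low values (0.0711).

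In the 3 other missense genotypes Chd8 passed no test against WT. At day 0 L834P/+ cells held 24.6 ± 0.634 TPM, R910Q/+ cells 23.1 ± 1.38 TPM and R1242Q/+ cells 23.1 ± 1.05 TPM, with fold changes of 0.03 ± 0.07, -0.06 ± 0.07 and -0.06 ± 0.07. Against CHD8+/- cells at day 0, Chd8 was higher in all 4 missense genotypes: L834P/+ (0.61 ± 0.07, adjusted p = 0.00101), R910Q/+ (0.52 ± 0.07, adjusted p = 0.0119), L1072F/+ (0.37 ± 0.07, adjusted p = 0.0111) and R1242Q/+ (0.52 ± 0.07, adjusted p = 0.0117). The R1242Q/+ difference ended without CHD8+/- b (0.0748), R1242Q/+ a (0.116) and R1242Q/+ c (0.0514), that of R910Q/+ without R910Q/+ a (0.0999) and R910Q/+ b (0.0815) and that of L1072F/+ without L1072F/+ b (0.0602), and all 4 ended with the spread of the compared groups alone (0.214 to 0.993). No missense genotype passed against CHD8+/- cells at days 8 or 14, where the adjusted p ran from 0.237 to 0.713. In WT cells Chd8 rose by 0.28 from day 0 to day 8 (-0.04 with median-of-ratios scaling, adjusted p = 0.472) and by 0.30 from day 8 to day 14.

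**Figure D1:**
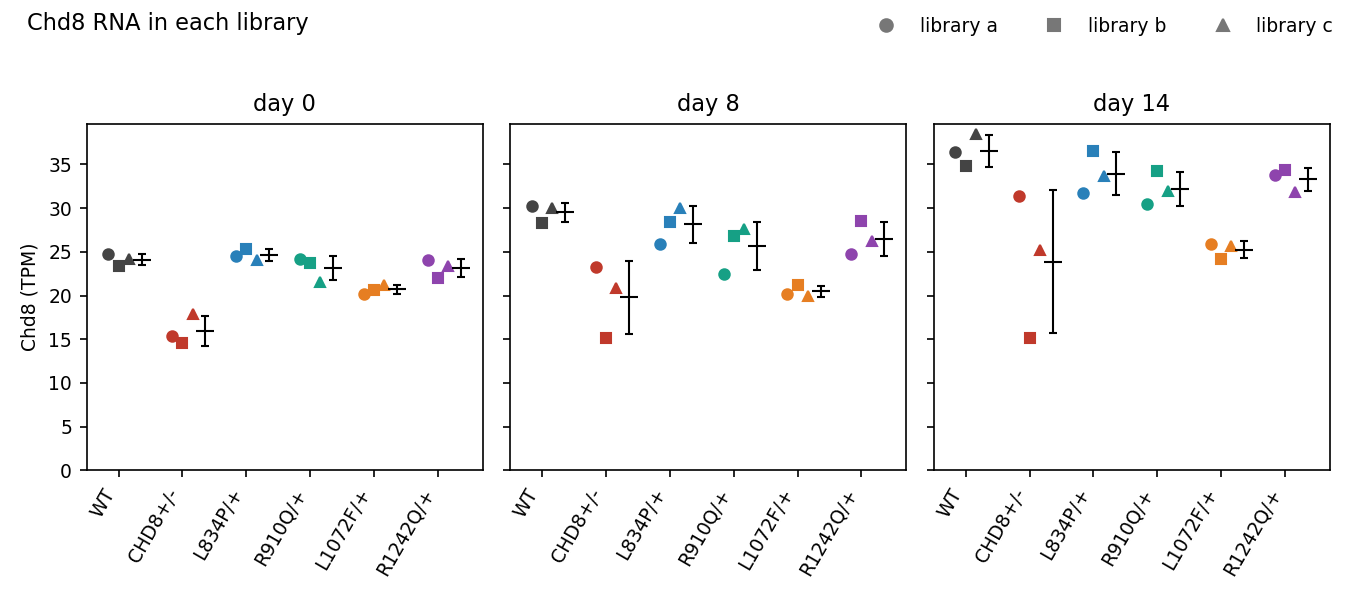
Chd8 level in TPM (vertical axis) in each library by genotype and day; circles, squares and triangles are libraries a, b and c, and the black dash and bar are the mean ± SD of 3 libraries. The day 0 means were 24.1 TPM in WT and 15.9 TPM in CHD8+/- cells.

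How many genes each genotype changed against WT was compared at each stage. L1072F/+ cells had the most: 1735 of 15958 genes at day 0, 10057 of 19408 at day 8 and 6486 of 21209 at day 14. Each of the 12 other comparisons called 9 genes or fewer. Leaving out 1 library gave up to 1252 genes in CHD8+/- (day 8) and 4 to 1567 in L1072F/+ (day 14). Without CHD8+/- b in any fit, R910Q/+ and R1242Q/+ gave far more at day 8 (below). No gene passed in the same direction in all 5 genotypes at any day, and 1 gene, the mitochondrial large ribosomal RNA mt-Rnr2, passed in 4 of them, at day 8.

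**Figure D2:**
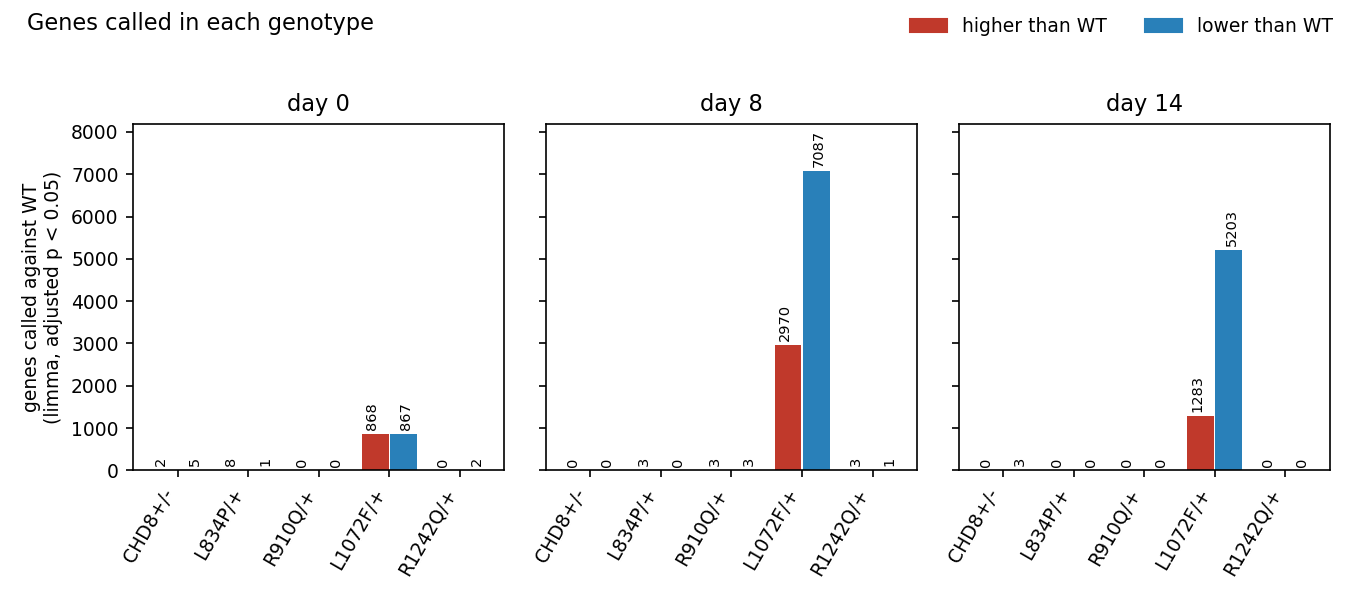
Number of genes called at adjusted p under 0.05 against WT (vertical axis, linear) by genotype and day, with rises and falls apart. L1072F/+ cells called 1735, 10057 and 6486 genes at days 0, 8 and 14.

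CHD8+/- cells were compared with WT cells to see what the loss of function of 1 allele changes. At day 0, Armcx2 fell from 9.57 ± 0.945 TPM to 5.24 ± 0.0787 TPM (-0.76 ± 0.07, adjusted p = 0.000229). Lmna, which encodes lamin A/C, fell by 0.52 and Ppfia4, a liprin, by 1.16; Chd8 and Gm26590, an unnamed model chosen after its values were seen, were the other falls (-0.61 ± 0.09). Adi1, of methionine salvage, rose by 0.39 and Mtrr, methionine synthase reductase, by 0.36, and both had 3 libraries above all 3 WT libraries. Of the glycolysis and hypoxia list, 0 of 27 rose and 0 fell over all genes, 0 and 10 adjusted over the list alone (median -0.39, camera adjusted p = 1.22e-08, 0.985 with an estimated correlation). Its members with the largest changes, Bnip3 and Egln3, gave -0.93 ± 0.37 and -0.88 ± 0.40 (over the list alone, adjusted p = 0.0575 and 0.0834). The count of 7 was 2 without WT a, b or c, 279 without CHD8+/- a and 3 without CHD8+/- b, and 0 with the spread of the compared groups alone and 3 without CHD8+/- b in any fit. Calls ended for Adi1, Mtrr and Lmna without WT a, b or c or CHD8+/- b or c (0.0660 to 0.139) and Ppfia4 and Gm26590 without WT a, b or c or CHD8+/- b (0.0660 to 0.118). Calls of all genes named here ended with the spread of the compared groups alone (0.409 to 0.494).

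At day 8, CHD8+/- cells had higher p53 targets and lower endoderm genes than WT cells by the list test, and 0 genes passed alone. Of the p53 list, 0 of 24 rose and 0 fell over all genes, 4 and 0 adjusted over the list alone (median 0.28, camera adjusted p = 2.26e-05, 0.759 with an estimated correlation). Pmaip1 stood at 32.1 ± 14.6 TPM against 14.0 ± 2.52 TPM (1.07 ± 0.26; over the list alone, adjusted p = 0.0123). Trp53inp1 gave 0.85 ± 0.22 and Mdm2 0.63 ± 0.17. Of the endoderm list, 0 of 16 rose and 0 fell over all genes, 0 and 8 adjusted over the list alone (median -0.99, camera adjusted p = 0.000119, 0.985 with an estimated correlation). Col4a1 gave -2.32 ± 0.64 and Foxa2 -2.26 ± 0.62. CHD8+/- b stood apart from a and c: its pluripotency genes lay 2.41 (log2) above the WT mean while a and c lay at -1.37 and 0.66, and its chromosome 8 genes had a median shift of 0.41. limma called 0 genes with 2572 at an unadjusted p under 0.05, and 1252 without CHD8+/- a and 55 without CHD8+/- c; 6 without the filter on low values and 4 with median-of-ratios scaling. Without CHD8+/- a, these 5 genes passed over all genes (adjusted p 0.0289 to 0.0478).

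At day 14, the genes of fibroblasts were lower in CHD8+/- than in WT cells by the list test. Of the fibroblast list, 0 of 13 rose and 0 fell over all genes, 0 and 12 adjusted over the list alone (median -1.74, camera adjusted p = 2.61e-08, 0.759 with an estimated correlation). Col1a1 gave -2.55 ± 0.61 (over the list alone, adjusted p = 0.00310), and Dcn stood at 13.4 ± 9.56 TPM against 51.5 ± 2.32 TPM (-2.21 ± 0.60). Of the mitochondrially encoded genes, 0 of 13 rose and 0 fell over all genes, 5 and 0 adjusted over the list alone (median 0.28, camera adjusted p = 1.25e-08, 0.759 with an estimated correlation); mt-Nd1 gave 0.65 ± 0.14 and mt-Atp6 0.48 ± 0.14. Of the neuron list, 0 of 31 rose and 0 fell, over all genes and adjusted over the list alone (median -0.96, camera adjusted p = 0.0192, 0.985 with an estimated correlation), with Gad1 at -1.39 ± 0.77 and Dcx at -1.37 ± 0.77. The neuron call ended with the spread of the compared groups alone (0.0803), and its median turned to 0.22 without CHD8+/- b, whose neuron genes lay at -2.94 against 0.31 and 0.09 in a and c, and whose chromosome 8 median was 0.41. Osr2, a zinc finger transcription factor, fell from 14.9 ± 1.91 TPM to 1.90 ± 0.923 TPM (-2.51 ± 0.33, adjusted p = 0.0232), and so did the unnamed models Gm12426 (-2.48 ± 0.35) and Gm12276 (-1.23 ± 0.16), chosen after their values were seen. The count of 3 was 0 without WT a, b or c or CHD8+/- b, 1 without CHD8+/- a and 561 without CHD8+/- c, and 9 without the filter on low values, 0 with the spread of the compared groups alone and 0 without CHD8+/- b in any fit. Calls ended for Osr2, Gm12426 and Gm12276 without WT a, b or c or CHD8+/- a or b (0.0568 to 0.224). Calls of all genes named here ended with the spread of the compared groups alone (0.253 to 0.288); without CHD8+/- c, Col1a1 and mt-Nd1 passed over all genes (adjusted p = 0.0372 and 0.0322).

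L834P/+ cells at day 0 had higher levels of 7 genes that lie on chromosome 11 between 34809185 and 46442721. Clint1, a clathrin interactor, rose from 22.3 ± 0.424 TPM to 36.6 ± 0.261 TPM (0.69 ± 0.06, adjusted p = 7.13e-05). Spdl1, a spindle protein (0.63 ± 0.07, adjusted p = 0.000741), Pank3, a pantothenate kinase (0.63 ± 0.07), Adam19, a metalloprotease (0.61 ± 0.07), and Thg1l, which modifies histidine tRNA (0.71 ± 0.12), rose too. So did Rars (0.49 ± 0.07), Med7 of the Mediator complex (0.59 ± 0.07) and the unnamed model Gm16033 (0.74 ± 0.09), these 3 chosen after their values were seen. Lmna fell by 0.54. The count of 9 was 17 without L834P/+ b, and 14 without the filter on low values and 2 with the spread of the compared groups alone. Calls ended for Thg1l without WT a, b or c or L834P/+ a or c (0.153 to 0.285), Lmna without WT a or b (0.0507 to 0.0611) and Rars without WT b or L834P/+ c (0.0690 to 0.0766). They ended also for Thg1l without the filter on low values or with median-of-ratios scaling (0.0685 to 0.0792) and Thg1l, Spdl1, Pank3, Lmna, Gm16033, Rars and Med7 with the spread of the compared groups alone (0.0733 to 0.0918).

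At day 8, L834P/+ cells kept higher Spdl1, from 20.4 ± 0.899 TPM in WT to 33.6 ± 1.30 TPM (0.69 ± 0.08, adjusted p = 0.00735), and higher Med7 (0.62 ± 0.09, adjusted p = 0.0378); mt-Rnr2 rose as well (0.91 ± 0.14, adjusted p = 0.0498). Of the CHD family and its partners, 0 of 17 rose and 0 fell, over all genes and adjusted over the list alone (median -0.15, camera adjusted p = 0.00728, 0.759 with an estimated correlation). No other gene passed in L834P/+ cells at day 8. The count of 3 was 0 without WT a or b or L834P/+ b and 1 without L834P/+ c. Calls ended for mt-Rnr2 without WT a, b or c or L834P/+ b or c (0.110 to 0.492), Spdl1 without WT a or b or L834P/+ b (0.0858 to 0.0974) and Med7 without WT a or b or L834P/+ b or c (0.201 to 0.328). They ended also for mt-Rnr2 with a pseudocount of 0.1 TPM or without the filter on low values (0.0509 to 0.0570) and all genes named here with the spread of the compared groups alone (0.113 to 0.263). At day 14 limma called 0 genes in L834P/+ cells, with 661 at an unadjusted p under 0.05, and 5 without the filter on low values.

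In R910Q/+ cells at day 0, genes of the FGF/ERK response stood below WT by the list test. Of that list, 0 of 15 rose and 0 fell over all genes, 0 and 2 adjusted over the list alone (median -0.13, camera adjusted p = 7.13e-05, 0.659 with an estimated correlation). The 2 were Egr1 and Fos, immediate early transcription factors: Egr1 stood at 0.235 ± 0.0951 TPM against 2.10 ± 0.702 TPM (-1.31 ± 0.19; over the list alone, adjusted p = 7.54e-05) and Fos gave -1.26 ± 0.19 (over the list alone, adjusted p = 7.54e-05). Neither passed over all genes, where limma called 0 genes with 479 at an unadjusted p under 0.05. There were 1 with a pseudocount of 0.1 TPM, 5 without the filter on low values and 1 without CHD8+/- b in any fit, and Egr1 passed in each of these 3 (adjusted p 0.00363 to 0.0495).

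At day 8, Ski fell in R910Q/+ cells from 112 ± 3.57 TPM to 69.2 ± 7.08 TPM (-0.69 ± 0.10, adjusted p = 0.0296), and Leng8 by 0.86. mt-Rnr2 rose from 169 ± 14.5 TPM to 337 ± 49.3 TPM (0.98 ± 0.14, adjusted p = 0.0269), and mt-Tt by 1.17. Gm11196 (0.73 ± 0.12) and 2510016D11Rik (-1.03 ± 0.13), chosen after their values were seen, were the other 2 of 6. Of the autism risk list, 0 of 64 rose and 0 fell over all genes, 0 and 5 adjusted over the list alone (median -0.26, camera adjusted p = 5.84e-05, 0.985 with an estimated correlation). Shank3 gave -0.62 ± 0.30 and Gigyf1 -0.60 ± 0.16. The count was 0 without WT a or b or R910Q/+ b or c, 2 without WT c and 3 without R910Q/+ a, and 2 with the spread of the compared groups alone and 483 without CHD8+/- b in any fit. Calls ended for mt-Tt, Leng8 and Gm11196 without WT a, b or c or R910Q/+ a, b or c (0.0592 to 0.295) and mt-Rnr2, Ski and 2510016D11Rik without WT a, b or c or R910Q/+ b or c (0.0567 to 0.199). Calls of all genes named here ended with the spread of the compared groups alone (0.0855 to 0.107), Ski with median-of-ratios scaling (0.0818) and Gm11196 without the filter on low values (0.0504). Gigyf1 passed without CHD8+/- b in any fit (adjusted p = 0.0188). At day 14 limma called 0 genes in R910Q/+ cells, with 1075 at an unadjusted p under 0.05, and 5 without the filter on low values. Pluripotency genes of R910Q/+ b lay at -2.19 from the WT mean there, those of a and c at 0.10 and -0.17; L834P/+ b lay at -1.79, R1242Q/+ a at -1.49 and CHD8+/- a at -3.05.

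L1072F/+ ES cells at day 0 had lower Wnt targets and primed pluripotency genes than WT cells. Lef1 fell from 3.55 ± 0.269 TPM to 1.17 ± 0.183 TPM (-1.07 ± 0.22, adjusted p = 0.00794), Sp5 by 0.75 and Ccnd1, cyclin D1, by 0.60. Of the Wnt list, 0 of 14 rose and 7 fell over all genes, 0 and 9 adjusted over the list alone (median -0.46, camera adjusted p = 8.92e-05, 0.799 with an estimated correlation). Pim2 and Dnmt3b fell by 0.82 and 0.72. Of the primed pluripotency list, 0 of 9 rose and 5 fell, over all genes and adjusted over the list alone (median -0.55, camera adjusted p = 0.000780, 0.759 with an estimated correlation). Egr1 and Fos fell by 0.96 and 0.90. Of the FGF/ERK list, 1 of 15 rose and 7 fell over all genes, 2 and 9 adjusted over the list alone (median -0.45, camera adjusted p = 0.000802, 0.659 with an estimated correlation). Krt8, a keratin, and Dsp, of desmosomes, rose by 1.21 and 0.85. Of the surface ectoderm list, 4 of 10 rose and 0 fell over all genes, 6 and 0 adjusted over the list alone (median 0.65, camera adjusted p = 0.000465, 0.759 with an estimated correlation).

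Among single genes at day 0, Rpph1, the RNA of RNase P, rose from 4.33 ± 2.12 TPM to 27.6 ± 4.58 TPM (2.51 ± 0.69, adjusted p = 0.0317), Chit1, a chitinase, by 1.72 and Thumpd3 by 1.46. Rhox5, an X-linked homeobox gene, fell from 40.0 ± 6.40 TPM to 7.16 ± 1.41 TPM (-2.33 ± 0.41, adjusted p = 0.00467). The pluripotency-associated noncoding RNAs Platr3 and Platr14 fell by 2.23 and 2.08, Accsl by 2.19 and Pnma5 by 2.00. In total 868 genes rose and 867 fell, and 379 of the rises were among the 752 genes of chromosome 8, of which 0 fell. The 3 libraries had chromosome 8 medians of 0.48, 0.47 and 0.45 (log2) above the WT mean, and without that chromosome 489 genes rose and 867 fell. The count was 699, 725 and 1062 without WT a, b and c, and 963, 671 and 861 without L1072F/+ a, b and c. It was 3704 with the spread of the compared groups alone. Calls ended for Rpph1 without WT a, b or c or L1072F/+ a, b or c (0.0631 to 0.105), Sp5 without WT a or b or L1072F/+ a or b (0.0551 to 0.108) and Fos without WT a (0.0535), and for Rpph1 and Sp5 without the filter on low values (0.0537 to 0.0696).

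At day 8, L1072F/+ cells had higher pluripotency genes and lower neural genes than WT cells. Tdgf1 stood at 78.9 ± 5.66 TPM against 5.61 ± 0.410 TPM (3.60 ± 0.87, adjusted p = 0.00456), and Dppa2 and Dppa4, pluripotency-associated genes, rose by 3.71 and 3.54. Of the pluripotency list, 20 of 24 rose and 0 fell over all genes, 21 and 0 adjusted over the list alone (median 2.76, camera adjusted p = 2.61e-08, 0.985 with an estimated correlation). Hes5 fell from 60.7 ± 5.38 TPM to 3.72 ± 2.07 TPM (-3.82 ± 0.58, adjusted p = 0.000724), Pax6 fell by 3.17, and the proneural factor Neurog2 fell too (adjusted p = 0.000656). Of the neural progenitor list, 0 of 22 rose and 19 fell, over all genes and adjusted over the list alone (median -2.41, camera adjusted p = 7e-05, 0.985 with an estimated correlation). Of the neuron list, 1 of 28 rose and 24 fell over all genes, 1 and 25 adjusted over the list alone (median -2.03, camera adjusted p = 0.000517, 0.985 with an estimated correlation). Nefm, a neurofilament, and Celf3 fell by 2.69 and 2.68, and Eomes rose by 2.44. Hoxd3 and Hoxb8 fell by 3.51 and 3.29. Of the Hox list, 0 of 27 rose and 22 fell over all genes, 0 and 23 adjusted over the list alone (median -2.23, camera adjusted p = 0.000426, 0.985 with an estimated correlation). In libraries a, b and c the pluripotency genes lay 2.61, 2.41 and 2.31 above the WT mean and the chromosome 8 medians were 0.45, 0.42 and 0.39; CHD8+/- b, the other library with such a chromosome 8 median (0.41), had 2.41.

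Genes of germ cells and of the two-cell-like state, an early embryonic programme, also rose in L1072F/+ cells at day 8. Dazl and Stra8, of germ cells, rose by 3.48 and 3.04. Of the germ cell list, 14 of 14 rose and 0 fell, over all genes and adjusted over the list alone (median 2.59, camera adjusted p = 1.58e-07, 0.985 with an estimated correlation). Zscan4f and Zscan4c rose by 2.77 and 2.77. Of the two-cell-like list, 12 of 12 rose and 0 fell, over all genes and adjusted over the list alone (median 2.43, camera adjusted p = 1.48e-06, 0.985 with an estimated correlation). Of the p53 targets, 13 of 24 rose and 0 fell over all genes, 13 and 1 adjusted over the list alone (median 0.43, camera adjusted p = 4.98e-05, 0.799 with an estimated correlation). Pmaip1 rose by 1.94, Perp by 1.56 and Trp53inp1 by 1.37. Of the autism risk genes, 4 of 64 rose and 42 fell over all genes, 4 and 43 adjusted over the list alone (median -0.53, camera adjusted p = 0.00133, 0.985 with an estimated correlation). Imprinted genes, expressed from 1 parental copy, went both ways: 5 of 29 rose and 11 fell over all genes, 5 and 13 adjusted over the list alone (median -0.83, camera adjusted p = 0.562, 0.991 with an estimated correlation). H19, an imprinted noncoding RNA, stood at 1689 ± 157 TPM against 69.6 ± 35.3 TPM (4.69 ± 1.03, adjusted p = 0.00285), and Mir675, which H19 hosts, rose by 4.83. Grb10, an imprinted inhibitor of growth, fell from 279.7 ± 7.75 TPM to 3.82 ± 0.377 TPM (-5.87 ± 0.47, adjusted p = 7.7e-05).

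The other largest rises in L1072F/+ cells at day 8 were of Rpph1 (3.79 ± 0.72) and the metallothionein Mt4 (3.73 ± 0.96), which lies on chromosome 8; the other largest falls were of Dbx1 (-4.58 ± 0.79), Mir219b (-4.30 ± 0.93), Nepn (-4.06 ± 1.40) and Unc5a, a netrin receptor (-4.06 ± 0.58). In total 2970 genes rose and 7087 fell (29.5% up). With median-of-ratios scaling 4803 rose and 4853 fell (49.7% up), since the median of all genes moved from -0.22 to -0.02; none of the list medians given here changed sign. Nepn was the named gene whose call ended, without WT a or b or L1072F/+ a, b or c (0.0529 to 0.0628). Without chromosome 8, 9639 genes were called.

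At day 14, neuronal genes and cholesterol genes were lower and ribosomal protein genes higher in L1072F/+ than in WT cells. Snap25 fell from 57.6 ± 5.63 TPM to 7.80 ± 1.13 TPM (-2.74 ± 0.72, adjusted p = 0.0246), and Elavl3 by 2.72. Of the neuron list, 1 of 31 rose and 22 fell over all genes, 1 and 27 adjusted over the list alone (median -2.10, camera adjusted p = 0.000106, 0.985 with an estimated correlation), the rise being of Eomes (1.35). Slc12a5 (-3.06) and Cplx1 (-2.88) fell. Of the REST-repressed genes, 0 of 29 rose and 27 fell over all genes, 1 and 28 adjusted over the list alone (median -2.32, camera adjusted p = 9.03e-06, 0.985 with an estimated correlation). Lss and Hmgcs1, enzymes of cholesterol synthesis, fell by 1.63 and 1.61. Of the cholesterol list, 0 of 24 rose and 18 fell over all genes, 0 and 19 adjusted over the list alone (median -0.92, camera adjusted p = 2.91e-05, 0.961 with an estimated correlation). Rpl13 rose by 1.12 and Rplp1 by 0.88. Of the cytosolic ribosomal proteins, 41 of 55 rose and 0 fell over all genes, 49 and 0 adjusted over the list alone (median 0.60, camera adjusted p = 1.28e-19, 0.985 with an estimated correlation). Cubn, of endoderm, rose by 2.38 and Rbp4 by 2.10. Of the endoderm list, 8 of 19 rose and 0 fell over all genes, 9 and 0 adjusted over the list alone (median 1.16, camera adjusted p = 3.36e-05, 0.985 with an estimated correlation). The chromosome 8 medians of the 3 libraries were 0.38, 0.38 and 0.36 above the WT mean, relative to all genes of the library.

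Pluripotency genes at day 14 stood above WT by the list test: 1 of 24 rose and 0 fell over all genes, 0 and 0 adjusted over the list alone (median 1.51, camera adjusted p = 4.19e-05, 0.985 with an estimated correlation). The called member was Fgf4 (1.86 ± 0.67, adjusted p = 0.0485); Zfp42 stood at 47.0 ± 1.17 TPM against 9.13 ± 1.79 TPM (2.26 ± 1.07) and Dppa2 gave 2.01 ± 1.04. H19 stood at 2655 ± 95.8 TPM against 92.3 ± 68.0 TPM (5.07 ± 1.31, adjusted p = 0.0239) and Mir675 rose by 5.16. Grb10 fell to 3.73 ± 0.329 TPM (-3.69 ± 0.52, adjusted p = 0.00876), and Zim1 and Peg13, also imprinted, fell by 3.29 and 4.74.

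The other largest rises at day 14 in L1072F/+ cells were of Mir450b (3.12 ± 1.07), Spink1 (2.58 ± 0.67) and Hpgd (2.58 ± 0.86), which lies on chromosome 8; the other largest falls were of Sncb, beta-synuclein (-3.61 ± 0.88), and Vsnl1, a neuronal calcium sensor (-3.42 ± 0.75). In total 1283 genes rose and 5203 fell (19.8% up). With median-of-ratios scaling 2467 rose and 3242 fell (43.2% up), as the median of all genes moved from -0.19 to 0.01. The count was 6, 1567 and 4 without WT a, b and c and 21, 4 and 20 without L1072F/+ a, b and c. It was 15009 with the spread of the compared groups alone, 11317 without CHD8+/- b in any fit and 6201 without chromosome 8. Calls ended for Mir675, H19, Spink1, Peg13, Sncb, Vsnl1, Rpl13, Lss, Hmgcs1 and Cubn without WT a or c or L1072F/+ a, b or c (0.0549 to 0.0851), Mir450b, Hpgd, Snap25, Elavl3, Slc12a5, Cplx1, Rplp1, Rbp4, Fgf4 and Eomes without WT a, b or c or L1072F/+ a, b or c (0.0522 to 0.147) and Grb10 and Zim1 without WT a or c or L1072F/+ b (0.0508 to 0.0650). They ended also for Mir450b, Hpgd, Fgf4 and Eomes with a pseudocount of 0.1 TPM (0.0638 to 0.158) and Mir450b, Hpgd, Rplp1, Fgf4 and Eomes without the filter on low values (0.0585 to 0.0848).

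**Figure D3:**
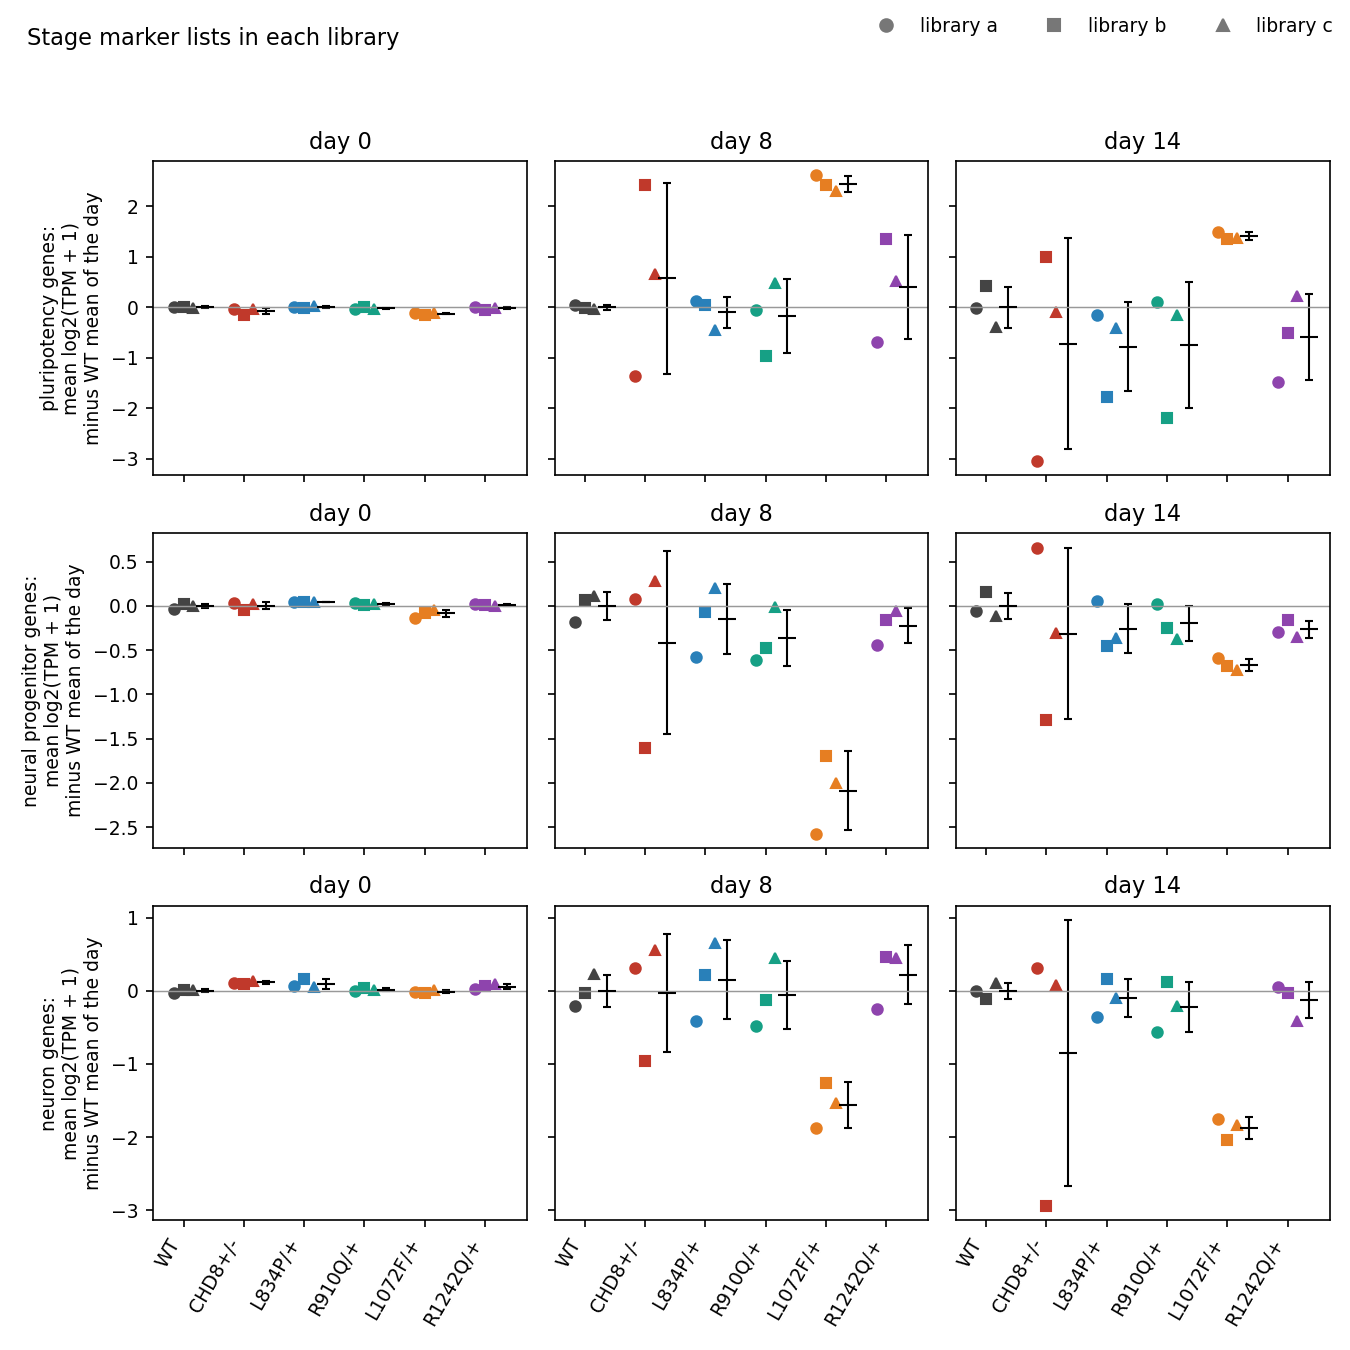
Mean log2(TPM + 1) of gene lists per library minus the WT mean of the same day (vertical axis), by genotype; circles, squares and triangles are libraries a, b and c, and the black dash and bar are the mean ± SD of 3 libraries. At day 8 the pluripotency list lay 2.31 to 2.61 above WT in the L1072F/+ libraries and 2.41 above it in CHD8+/- b.

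R1242Q/+ cells at day 0 had lower Fos, at 0.998 ± 0.540 TPM against 5.05 ± 1.06 TPM in WT cells (-1.62 ± 0.19, adjusted p = 0.00894). The unnamed model Gm48974, chosen after its values were seen, was the other of 2 calls (-2.37 ± 0.32). Of the cytosolic ribosomal proteins, 0 of 55 rose and 0 fell over all genes, 0 and 12 adjusted over the list alone (median -0.08, camera adjusted p = 7.9e-11, 0.759 with an estimated correlation). The count was 0 without WT a or c or R1242Q/+ a, 1 without WT b and 8 without R1242Q/+ c, and 8 with a pseudocount of 0.1 TPM, 8 without the filter on low values, 7 with median-of-ratios scaling and 0 with the spread of the compared groups alone. Calls ended for Fos without WT a or c or R1242Q/+ a (0.0663 to 0.0959) and Gm48974 without WT a, b or c or R1242Q/+ a (0.0749 to 0.142). Calls of all genes named here ended with the spread of the compared groups alone (0.285 to 0.406).

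At day 8, mt-Rnr2 rose in R1242Q/+ cells from 169 ± 14.5 TPM to 403 ± 15.6 TPM (1.25 ± 0.14, adjusted p = 0.00345), and the mitochondrial tRNAs mt-Ta and mt-Tw by 1.18 and 1.17. Ski fell to 65.8 ± 2.79 TPM (-0.76 ± 0.10, adjusted p = 0.0198). Of the autism risk list, 0 of 64 rose and 0 fell over all genes, 0 and 7 adjusted over the list alone (median -0.25, camera adjusted p = 0.000720, 0.985 with an estimated correlation). Shank3 gave -0.90 ± 0.30 and Tcf7l2 -0.70 ± 0.23. Library b, with a chromosome 8 median of 0.12, had pluripotency genes 1.36 above the WT mean, against -0.70 and 0.52 in a and c. The count of 4 was 1 without WT a or b or R1242Q/+ a, b or c, and 13 without the filter on low values, 15 with median-of-ratios scaling, 1 with the spread of the compared groups alone and 1564 without CHD8+/- b in any fit; with the scaling 9 genes rose and 6 fell. Calls ended for mt-Ta and mt-Tw without WT a, b or c or R1242Q/+ a, b or c (0.0785 to 0.271) and Ski without WT a or b or R1242Q/+ a, b or c (0.0785 to 0.183), and for mt-Ta, mt-Tw and Ski with the spread of the compared groups alone (0.0530); Tcf7l2 passed without CHD8+/- b in any fit (adjusted p = 0.00721). At day 14 limma called 0 genes in R1242Q/+ cells, with 1169 at an unadjusted p under 0.05, and 5 without the filter on low values and 1 without CHD8+/- b in any fit.

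Genes encoded by mitochondrial DNA, which make subunits of the respiratory chain, stood above WT at day 14 in 3 missense genotypes by the list test. In L834P/+ cells, 0 of 13 rose and 0 fell, over all genes and adjusted over the list alone (median 0.31, camera adjusted p = 1.36e-16, 0.659 with an estimated correlation); mt-Nd3 gave 0.52 ± 0.18 and mt-Cytb 0.37 ± 0.13. In R910Q/+ cells, 0 of 13 rose and 0 fell, over all genes and adjusted over the list alone (median 0.27, camera adjusted p = 4.75e-14, 0.659 with an estimated correlation); mt-Nd3 gave 0.51 ± 0.18 and mt-Co3 0.35 ± 0.12. In R1242Q/+ cells, 0 of 13 rose and 0 fell over all genes, 1 and 0 adjusted over the list alone (median 0.26, camera adjusted p = 1.56e-13, 0.659 with an estimated correlation); mt-Nd3 gave 0.48 ± 0.18 and mt-Co3 0.45 ± 0.12. At day 8 mt-Rnr2 rose in L834P/+, R910Q/+, L1072F/+ (0.75 ± 0.14, adjusted p = 0.00116) and R1242Q/+ cells, and in CHD8+/- cells it gave 0.69 ± 0.14 (adjusted p = 0.107). Every mutant library at day 14 had fewer genes at 1 TPM or more (19389 to 21140) than every WT library (21372 to 21494). Mitochondrial genes took 8.39% (L1072F/+ b) to 11.1% of the TPM in mutant libraries against 7.46% to 8.80% in WT, so these ranges overlapped.

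Each missense genotype was compared with CHD8+/- cells, since a change seen in 1 genotype alone is no difference between them. At day 0 L834P/+ cells had higher Adam19 (0.73 ± 0.07, adjusted p = 0.000250) and Lsm11 (0.73 ± 0.09), both on chromosome 11, among 10 rises and 0 falls. R910Q/+ cells had higher Armcx2 (0.72 ± 0.07, adjusted p = 0.000434) and Ppfia4 (1.07 ± 0.16) and lower Egr1 (-1.36 ± 0.19) and Mir6910 (-1.42 ± 0.24), among 5 rises and 4 falls. R1242Q/+ cells had lower Fos (-1.58 ± 0.19) and Egr1 (-1.22 ± 0.19), among 2 rises and 4 falls. At day 8 L834P/+ cells had higher Spdl1 (0.58 ± 0.08, adjusted p = 0.0425) among 2 rises and 0 falls.

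L1072F/+ cells had less Grb10 than CHD8+/- cells at each day. It was lower at day 0 (-1.99 ± 0.17, adjusted p = 5.45e-05), at day 8 (-5.12 ± 0.47, adjusted p = 0.000460) and at day 14 (-2.81 ± 0.52, adjusted p = 0.00825). H19 was higher at day 8 (5.07 ± 1.03) and day 14 (5.68 ± 1.31), as was Mir675 (5.31 ± 1.06 and 5.66 ± 1.35). At day 0 Ndufa4l2 and Mir1199 were higher (2.51 ± 0.55 and 2.19 ± 0.49) and Ptprtos lower (-2.15 ± 0.57). Hoxb9 was lower at day 8 (-4.02 ± 0.68) and Mir485 at day 14 (-2.35 ± 0.57). The counts were 505 rises and 465 falls at day 0, 933 and 4421 at day 8 (median-of-ratios scaling, 2237 and 2695), and 1470 and 1358 at day 14 (with that scaling 1921 and 1124). These counts moved with each library left out, upward only without CHD8+/- b, which has the chromosome 8 shift of the L1072F/+ libraries. At day 0 there were 199, 3221 and 241 without CHD8+/- a, b and c, and 243, 68 and 455 without L1072F/+ a, b and c. In the same order there were 695, 10472 and 1894, and 1367, 3086 and 2472 at day 8. At day 14 there were 553, 13468 and 1406, and 555, 298 and 376. With the spread from the compared groups alone 0 genes were called at each day, and day 0 gave 432 without the filter on low values, where Ndufa4l2, Mir1199 and Ptprtos ended (adjusted p 0.0508 to 0.0839). At day 0 calls ended for Ndufa4l2 without CHD8+/- a or c or L1072F/+ a or b (0.0571 to 0.122), Mir1199 without CHD8+/- a or c or L1072F/+ b or c (0.0566 to 0.125) and Ptprtos without CHD8+/- a or c or L1072F/+ a, b or c (0.0910 to 0.163); at day 14, for H19, Mir675 and Mir485 without CHD8+/- a or c or L1072F/+ a, b or c (0.0553 to 0.0997).

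The smaller counts against CHD8+/- cells moved with single libraries. For L834P/+ day 0 the count of 10 was 190 without CHD8+/- a and 20 without L834P/+ b. For R910Q/+ day 0 the 9 were 194 without CHD8+/- a, 4 without CHD8+/- b or c, 1 without R910Q/+ a or b and 5 without R910Q/+ c. Calls ended for Ppfia4 without CHD8+/- b or c or R910Q/+ a or b (0.0540 to 0.212), Mir6910 without CHD8+/- b or c or R910Q/+ a, b or c (0.0780 to 0.282) and Egr1 without R910Q/+ a or b (0.0846 to 0.106), for Ppfia4 and Mir6910 without the filter on low values (0.0682 and 0.104) and for Mir6910 with median-of-ratios scaling (0.0533), where 5 genes rose and 2 fell. For R1242Q/+ day 0 the 6 were 84, 1 and 3 without CHD8+/- a, b and c. Without R1242Q/+ a, b and c they were 0, 3 and 1. Calls ended for Fos without R1242Q/+ a or c (0.0514 to 0.112) and Egr1 without CHD8+/- b or R1242Q/+ a, b or c (0.116 to 0.139), and for Egr1 without the filter on low values (0.0660). For L834P/+ day 8 the 2 were 9, 1 and 7 without CHD8+/- a, b and c and 0 without L834P/+ a, b or c. Spdl1 ended as a call without CHD8+/- c or L834P/+ a, b or c (0.0526 to 0.211) and with median-of-ratios scaling (0.0995). With the spread of the compared groups alone each of these 4 counts was 0. limma called 0 genes for R910Q/+ at day 8 (2698 at an unadjusted p under 0.05; 3 without CHD8+/- a, 150 without CHD8+/- b and 83 without CHD8+/- c) and R1242Q/+ at day 8 (1973; 199 without CHD8+/- b and 6 without CHD8+/- c). At day 14 it called 0 for L834P/+ (2337; 451 without CHD8+/- c), R910Q/+ (2910; 18 without CHD8+/- a, 837 without CHD8+/- b and 647 without CHD8+/- c) and R1242Q/+ (2694; 11 without CHD8+/- a, 614 without CHD8+/- b and 573 without CHD8+/- c).

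Likeness of missense and CHD8+/- fold changes against WT was measured by Pearson's r across genes, in 12 pairs. Genes are not independent replicates, and the shared WT libraries alone gave a simulated mean r of 0.121 to 0.405. Real libraries also varied together across genes, which the simulations may lack, so a higher r need not come from the genotype. At day 8 R1242Q/+ and L1072F/+ cells had the highest r, 0.743 over 19408 genes (simulated mean 0.217) and 0.715 (0.283). L834P/+ and R910Q/+ cells had 0.535 (0.233) and 0.488 (0.218). At day 0 L834P/+, R910Q/+, L1072F/+ and R1242Q/+ cells had 0.502 (0.390), 0.403 (0.374), 0.393 (0.405) and 0.502 (0.364), and at day 14 0.318 (0.125), 0.338 (0.121), 0.462 (0.193) and 0.413 (0.140). The values for L1072F/+ rested on CHD8+/- b: without it r was 0.09, 0.12 and -0.44 at days 0, 8 and 14, and for R1242Q/+ 0.34, 0.54 and 0.19. At day 14 it was 0.72 for L1072F/+ without CHD8+/- a and 0.22 for R1242Q/+ without R1242Q/+ c. For L834P/+ at day 14 r was 0.12, 0.46 and 0.21 without CHD8+/- a, b and c and 0.19 without L834P/+ c. For R910Q/+ at day 14 it was 0.44 without WT b, 0.20 without CHD8+/- b, and 0.22 and 0.23 without R910Q/+ a and c. At day 8 it was 0.14 without R910Q/+ c.

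Whether a genotype's effect differed between day 14 and day 0 was tested as an interaction over 20204 genes. In L1072F/+ cells Mir675 and Rhox5 moved up relative to WT (4.70 ± 1.60 and 4.15 ± 1.43, adjusted p = 0.0256 and 0.0268), and Peg13 and Sncb moved down (-4.12 ± 0.98 and -4.00 ± 0.81, adjusted p = 0.00393 and 0.00173), among 1460 rises and 4682 falls (median-of-ratios scaling, 2083 and 3976). In CHD8+/- cells Srxn1 (1.14 ± 0.22, adjusted p = 0.0220) and Pgam5 (0.44 ± 0.09) moved up, and Nap1l5 (-3.58 ± 0.70, adjusted p = 0.0225) and Col15a1 (-2.55 ± 0.47) moved down, among 2 rises and 22 falls (with that scaling 7 and 25). In R1242Q/+ cells Snord83b moved down (-1.66 ± 0.28, adjusted p = 0.0139). For L834P/+ and R910Q/+ limma called 0 genes, with 494 and 494 at an unadjusted p under 0.05. In L1072F/+ cells calls ended for Mir675 without WT day 0 b, L1072F/+ day 0 a or WT day 14 a or c (0.0567 to 0.0619) and Rhox5 without L1072F/+ day 0 a or WT day 14 c (0.0506 to 0.0537), and for Mir675 with a pseudocount of 0.1 TPM (0.0552). The CHD8+/- count was 8 without WT day 0 a, b or c or WT day 14 c. It was 6 and 5 without WT day 14 a and b, and 14 and 10 without CHD8+/- day 0 b and c. Without CHD8+/- day 14 a and c it was 168 and 1455. Calls ended for Srxn1 without WT day 0 a, CHD8+/- day 0 c or WT day 14 a or b (0.0597 to 0.0922), Pgam5 without WT day 0 b or c, CHD8+/- day 0 c, WT day 14 a, b or c or CHD8+/- day 14 b (0.0617 to 0.132), Nap1l5 without WT day 0 a, b or c, CHD8+/- day 0 b or WT day 14 a, b or c (0.0577 to 0.0776) and Col15a1 without WT day 14 b (0.0577). Calls of these 4 genes ended with the spread of the compared groups alone (0.261 to 0.708) and Nap1l5 and Col15a1 with a pseudocount of 0.1 TPM (0.107 to 0.192). The R1242Q/+ count was 0 without WT day 0 b or c or WT day 14 a or c. It was 0 too without R1242Q/+ day 0 c or R1242Q/+ day 14 a or b, and 2 without R1242Q/+ day 0 b. Where it was 0 Snord83b ended as a call (0.0757 to 0.151), as it did with the spread of the compared groups alone (0.0712). L834P/+ gave 5 without L834P/+ day 14 a.

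Medians of the genes of each chromosome were compared between libraries. Chromosome 8 medians lay at 0.36 to 0.48 (log2) in all 9 L1072F/+ libraries and at 0.47, 0.41 and 0.41 in CHD8+/- b at days 0, 8 and 14. The 42 other libraries lay between -0.05 and 0.19 (R1242Q/+ b at day 0). Chromosome 6 medians of the 45 mutant libraries ran from -0.24 to 0.19, with 14 under -0.1 and 8 over 0.1, and each mutant group but those of L1072F/+ had libraries on both sides of 0. In L834P/+, R910Q/+ and R1242Q/+ cells each letter kept its side at all 3 days. At day 14 CHD8+/- b also had chromosome 11 at 0.26 (0.15 in a) and chromosome 18 at -0.21, and L1072F/+ a, b and c had chromosome 13 at 0.16, 0.15 and 0.19. At day 0, 379 of 752 chromosome 8 genes rose in L1072F/+ cells and 0 fell (median 0.42); 277 of 878 rose and 141 fell at day 8, and 181 of 950 rose and 104 fell at day 14. None of the 300 chromosome tests passed with an estimated correlation (chromosome 8 of L1072F/+: adjusted p = 0.997, 0.997 and 0.630). The shift of CHD8+/- b enters that estimate, so these 3 tests cannot decide.

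**Figure D4:**
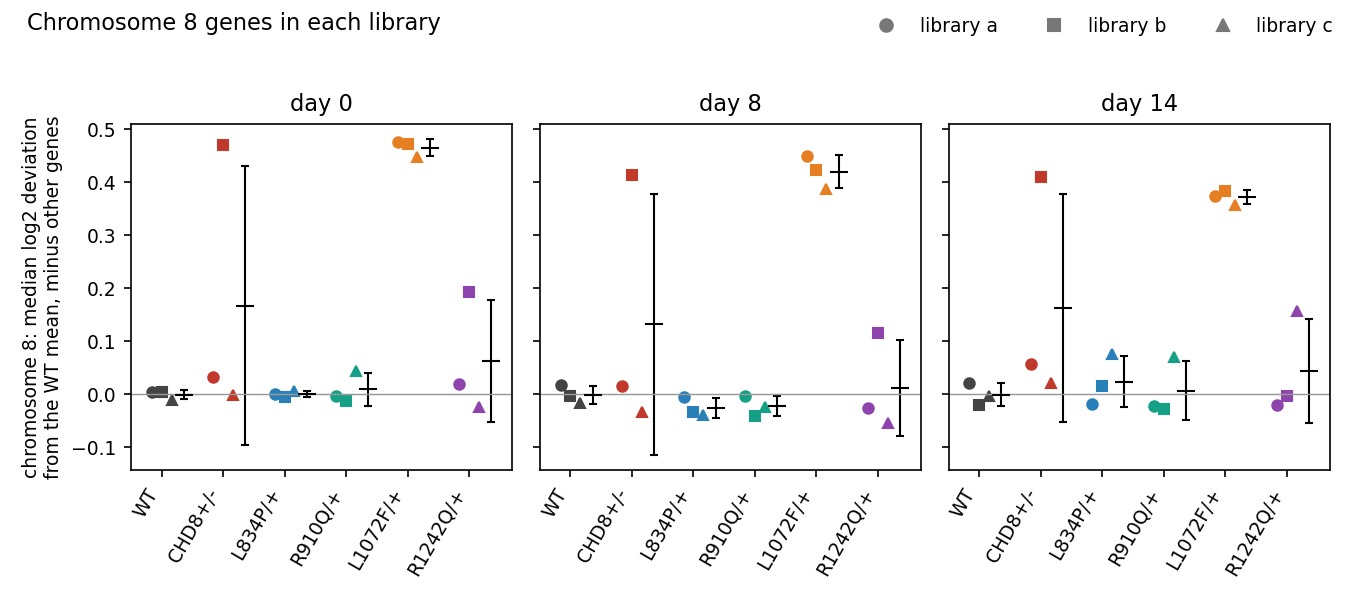
Median log2 deviation of chromosome 8 genes from the WT mean of the same day (vertical axis) in each library, by genotype and day; circles, squares and triangles are libraries a, b and c, and the black dash and bar are the mean ± SD of 3 libraries. The 9 L1072F/+ libraries lie between 0.36 and 0.48, and CHD8+/- b lies at 0.47, 0.41 and 0.41.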

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

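The tests of a chromosome 8 gain at day 8, of the L1072F allele, of CHD8+/- b and of an extra copy on chromosome 11 were chosen after their results were seen. Groups held 3 libraries each, too few to test a single library as an outlier.

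Effects of a genotype differed between days 0 and 14 for 24 genes in CHD8+/- cells by the interaction test. Srxn1 (1.14) and Pgam5 (0.44) moved up, and Nap1l5 (-3.58) and Col15a1 (-2.55) moved down. When the libraries of CHD8+/- and WT cells were regrouped in 100 drawn splits, 1 split, the real one, gave as many (the highest other gave 22). These splits take libraries of different days as unrelated, while CHD8+/- b had raised chromosome 8 genes at all 3 days and CHD8+/- a and b each kept their side in chromosome 6, so chance stays open. The count ran from 5 without WT day 14 b to 1455 without CHD8+/- day 14 c. In L1072F/+ cells 6142 genes differed, with Mir675 (4.70) and Rhox5 (4.15) up and Peg13 (-4.12) and Sncb (-4.00) down. As many came from 5 of 100 splits (highest other 7623), but the 4 others kept the real groups of day 0, and the 87 splits that kept those of neither day gave 0, so the share leaves chance open. In R1242Q/+ cells Snord83b (-1.66) was the 1 gene, and 12 of 100 splits gave as many (highest other 4), each of the 11 others keeping the real groups of 1 day, so chance stays open there. For L834P/+ and R910Q/+ the count was 0, which limma gave with 494 genes each at an unadjusted p under 0.05, and all 100 splits gave as many (highest other 1 and 5).

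L1072F/+ libraries at day 8 had high pluripotency and low neural genes, and all 9 L1072F/+ libraries had raised chromosome 8 genes. A plain mixture of undifferentiated and WT-like cells is argued against: the share read from genes high at day 0 and the share read from genes high at day 8 added up to 0.358 (bootstrap 0.327 to 0.409), where a mixture needs 0.8 to 1.2 and the lowest library outside L1072F/+ and CHD8+/- b gave 0.766. A gain of chromosome 8 is a candidate explanation: CHD8+/- b, with the same shift, moved from a and c as L1072F/+ moved from WT. Pearson's r across genes outside chromosome 8 (not independent replicates) was 0.861 at day 8 and 0.463 at day 0. R1242Q/+ b came next (0.506 and 0.278), with smaller chromosome 8 rises (0.12 and 0.19). The axis is not particular to the gain. R910Q/+ c gave 0.263 at day 0 with a median of 0.04. At day 14 CHD8+/- b gave 0.852, but R910Q/+ a gave 0.645 and L834P/+ a 0.519 without a rise (both -0.02). R1242Q/+ c gave 0.715 with a smaller rise (0.16). The L1072F allele itself cannot be told apart from the gain, because 0 of 9 L1072F/+ libraries lacked it.

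CHD8+/- b stood apart from a and c at days 8 and 14. A mislabelled L1072F/+ library is argued against by Grb10 and H19 in b at day 8 (log2 5.71 and 8.09). The nearer, H19, lay 2.629 from its L1072F/+ mean. Both lay between the L1072F/+ and WT (8.13 and 6.03) means, so a mixture stays open. A gain of chromosome 8 may set b apart, with a median at least 0.313 above a and c at each day. Named by order, b need not be the same culture at each day. Lower RNA quality stays open, since b had 19624 genes at 1 TPM or more at day 8, the most of 18 libraries, and the fewest at day 14 (19389); its mitochondrial share of TPM, 6.74% and 9.65%, lay inside the range of the other libraries (up to 7.20% and 11.1%), which goes against it.

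The 7 chromosome 11 genes that rose in L834P/+ cells at day 0, Spdl1, Pank3, Rars, Clint1, Thg1l, Adam19 and Med7, lie between 34809185 and 46442721. They do not form a single run. Spdl1, Pank3 and Rars end at 35834528, Clint1, Thg1l, Adam19 and Med7 start at 45851944, and none of the 7 lies between these positions. An extra copy stays open: at days 0, 8 and 14 the median of all tested genes in between was 0.17 (log2), 0.20 and 0.154, and without the 7 it was 0.12, 0.10 and 0.10 (0.04, 0.03 and 0.04 in the 5 Mb before). The 7 were picked by their rise and set the interval, so neither median settles it. Reads shared by overlapping genes are argued against, since 0 of 7 overlap another. The L834P allele and a change of sequence beside these genes stay open and were not tested.

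Each count of called genes was also set against the other splits of the same 6 libraries, of which there are 10. With 10 splits no share under 0.05 can be had. Against WT, 1 split, the real one, gave as many genes in 10 comparisons: the real count and the highest other were 7 against 2 for CHD8+/- day 0, 3 against 0 for CHD8+/- day 14, 9 against 1 for L834P/+ day 0, 3 against 0 for L834P/+ day 8, 6 against 0 for R910Q/+ day 8, 1735 against 0 for L1072F/+ day 0, 10057 against 0 for L1072F/+ day 8, 6486 against 0 for L1072F/+ day 14, 2 against 1 for R1242Q/+ day 0 and 4 against 0 for R1242Q/+ day 8. In the other 5, CHD8+/- day 8, L834P/+ day 14, R910Q/+ day 0, R910Q/+ day 14 and R1242Q/+ day 14, limma called 0 genes, all 10 splits gave as many and the highest other was 0; at an unadjusted p under 0.05 there were 2572, 661, 479, 1075 and 1169. Between WT days, 1 split, the real one, gave as many, with 15857 against 0 for days 0 and 8 and 14342 against 0 for days 8 and 14.

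Against CHD8+/- cells the same holds of the 10 splits. As many genes came from 1 split, the real one, for L834P/+ day 0 (10 against 2 in the highest other), R910Q/+ day 0 (9 against 1), L1072F/+ day 0 (970 against 1) and L1072F/+ day 8 (5354 against 2589). They came from 2 splits for R1242Q/+ day 0 (6 against 1287) and L834P/+ day 8 (2 against 38) and from 3 for L1072F/+ day 14 (2828 against 5007). Where limma called 0, all 10 splits gave as many, the highest other being 808 for R910Q/+ day 8, 486 for R1242Q/+ day 8, 2 for L834P/+ day 14, 6275 for R910Q/+ day 14 and 2030 for R1242Q/+ day 14, and an unadjusted p under 0.05 was reached by 2698, 1973, 2337, 2910 and 2694 genes. Splits with many more genes than the real one point to a structure of the samples other than the genotypes.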

How the results depend on the processing

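The alternatives that were added after the result was seen leave out CHD8+/- b of each day or, for L1072F/+, the genes of chromosome 8; the others were fixed at the start. No paired analysis was possible because the columns of the table carry no replicate numbers, so the planned replicate block was not run. Their order carries structure that no fit uses: Eif2s3y, looked at after the results were seen, was lower in a than in c in 18 of 18 groups. A fit of the compared groups alone gives no similarity value. TPM holds no counts, so the depth behind each value is unknown and low values cannot be told from sampling noise. Counting values of single named genes that kept their direction and side of the threshold, calls ended and calls added, leaving out 1 library at a time kept 990, ended 334 and added 8, the compared groups alone 155, 56 and 2, no filter 196, 16 and 1, the pseudocount 204, 8 and 1, scaling 209, 4 and 0, and leaving out CHD8+/- b 144, 12 and 4. Of called values, Chd8 between WT days 0 and 8 turned with scaling (below); of uncalled ones, Chd8 of L1072F/+ against CHD8+/- days 8 and 14 turned without CHD8+/- b (-0.11 and -0.15). For lists, leaving out 1 library at a time kept 1394, ended 192 and added 31, the compared groups alone 246, 12 and 12, no filter 244, 18 and 8, the pseudocount 265, 5 and 0, scaling 244, 20 and 6, and leaving out CHD8+/- b 199, 22 and 4, and the estimated correlation kept 60 and ended 210. Of the list medians, 3 turned, given below. The 7 counts of L1072F/+ without chromosome 8 stayed within 1.5 times, and the 15 chromosome 8 medians over genes with a mean of at least 5 TPM kept their direction and side. Leaving out a library or a group lowers the number of samples, and leaving out the filter raises the number of genes tested; beyond that, the cause was not tested for any change below.

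With a pseudocount of 0.1 TPM, the genes called against WT numbered 1 for R910Q/+ day 0 and 8 for R1242Q/+ day 0. The genes called against CHD8+/- numbered 10 for R1242Q/+ day 0. The genes called for the change of effect between days 0 and 14 numbered 9 for CHD8+/- and 2 for R1242Q/+. Chd8 against WT changed by -0.53 (adjusted p = 0.0508) for L1072F/+ day 14.

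Without the filter on low values, the genes called against WT numbered 14 for L834P/+ day 0, 5 for R910Q/+ day 0 and 14, L834P/+ day 14 and R1242Q/+ day 14, 8 for R1242Q/+ day 0, 6 for CHD8+/- day 8, 13 for R1242Q/+ day 8 and 9 for CHD8+/- day 14. The genes called against CHD8+/- numbered 432 for L1072F/+ day 0, 1 for R910Q/+ day 8, L834P/+ day 14 and R1242Q/+ day 14, 4 for R1242Q/+ day 8 and 3 for R910Q/+ day 14. The genes called for the change of effect between days 0 and 14 numbered 64 for CHD8+/-, 17 for L834P/+, 14 for R910Q/+ and 15 for R1242Q/+. Chd8 against WT changed by -0.52 (adjusted p = 0.0711) for L1072F/+ day 14. The gene lists called against WT numbered 3 for R1242Q/+ day 0 and 9 for R1242Q/+ day 14.

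With median-of-ratios scaling, the genes called against WT numbered 7 for R1242Q/+ day 0, 4 for CHD8+/- day 8 and 15 for R1242Q/+ day 8. The genes called against CHD8+/- numbered 1 for L834P/+ day 8 and 20 for R910Q/+ day 14. The genes called for the change of effect between days 0 and 14 numbered 2 for R1242Q/+. Chd8 against WT changed by -0.29 (adjusted p = 0.111) for L1072F/+ day 14. Chd8 between WT stages changed by -0.043 (adjusted p = 0.472) for WT day 8 against day 0. The gene lists called against WT numbered 3 for R910Q/+ day 0 and 10 for R1242Q/+ day 14.

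With the spread of the compared groups alone, the genes called against WT numbered 0 for CHD8+/- day 0 and 14 and R1242Q/+ day 0, 2 for L834P/+ day 0 and R910Q/+ day 8, 3704 for L1072F/+ day 0, 1 for R1242Q/+ day 8 and 15009 for L1072F/+ day 14. The genes called against CHD8+/- numbered 0 for L834P/+ day 0 and 8, R910Q/+ day 0, L1072F/+ day 0, 8 and 14 and R1242Q/+ day 0. The genes called for the change of effect between days 0 and 14 numbered 13171 for L1072F/+ and 0 for R1242Q/+. Chd8 against WT changed by -0.58 (adjusted p = 0.409) for CHD8+/- day 0 and -0.21 (adjusted p = 0.0175) for L1072F/+ day 0. Chd8 against CHD8+/- changed by 0.61 (adjusted p = 0.474) for L834P/+ day 0, 0.52 (adjusted p = 0.936) for R910Q/+ day 0, 0.37 (adjusted p = 0.214) for L1072F/+ day 0 and 0.52 (adjusted p = 0.993) for R1242Q/+ day 0. The gene lists called against WT numbered 3 for R1242Q/+ day 0, 13 for R910Q/+ day 8 and 14 for R1242Q/+ day 14.

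Without CHD8+/- b in any fit, an alternative chosen after seeing the data, the genes called against WT numbered 3 for CHD8+/- day 0, 1 for R910Q/+ day 0 and R1242Q/+ day 14, 483 for R910Q/+ day 8, 1564 for R1242Q/+ day 8, 0 for CHD8+/- day 14 and 11317 for L1072F/+ day 14. The genes called against CHD8+/- numbered 4 for R910Q/+ day 0, 3221 for L1072F/+ day 0, 1 for R1242Q/+ day 0 and L834P/+ day 8, 150 for R910Q/+ day 8, 10472 for L1072F/+ day 8, 199 for R1242Q/+ day 8, 837 for R910Q/+ day 14, 13468 for L1072F/+ day 14 and 614 for R1242Q/+ day 14. The genes called for the change of effect between days 0 and 14 numbered 1 for R910Q/+ and 9741 for L1072F/+. Chd8 against WT changed by -0.21 (adjusted p = 0.0316) for L1072F/+ day 0. Chd8 against CHD8+/- changed by 0.46 (adjusted p = 0.0748) for R1242Q/+ day 0. The gene lists called against WT numbered 9 for R1242Q/+ day 14. The list median of CHD8+/- day 14 turned to 0.22 for neuron, 0.24 for REST-repressed neuronal genes and 0.15 for clustered protocadherins. The similarity r with CHD8+/- was 0.094 for L1072F/+ day 0, 0.34 for R1242Q/+ day 0, 0.12 for L1072F/+ day 8, 0.54 for R1242Q/+ day 8, 0.46 for L834P/+ day 14, 0.20 for R910Q/+ day 14, -0.44 for L1072F/+ day 14 and 0.19 for R1242Q/+ day 14.

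With an estimated correlation between genes, 0 gene lists were called in each of the 17 comparisons with list tests, where the preset correlation called 1 to 25.

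Leaving out 1 library at a time, the genes called against WT numbered 2 to 279 for CHD8+/- day 0, 6 to 17 for L834P/+ day 0, 671 to 1062 for L1072F/+ day 0, 0 to 8 for R1242Q/+ day 0, 0 to 1252 for CHD8+/- day 8, 0 to 4 for L834P/+ day 8, 0 to 3 for R910Q/+ day 8, 1 to 6 for R1242Q/+ day 8, 0 to 561 for CHD8+/- day 14 and 4 to 1567 for L1072F/+ day 14. The genes called against CHD8+/- numbered 8 to 190 for L834P/+ day 0, 1 to 194 for R910Q/+ day 0, 68 to 3221 for L1072F/+ day 0, 0 to 84 for R1242Q/+ day 0, 0 to 9 for L834P/+ day 8, 0 to 150 for R910Q/+ day 8, 695 to 10472 for L1072F/+ day 8, 0 to 199 for R1242Q/+ day 8, 0 to 451 for L834P/+ day 14, 0 to 837 for R910Q/+ day 14, 298 to 13468 for L1072F/+ day 14 and 0 to 614 for R1242Q/+ day 14. The genes called for the change of effect between days 0 and 14 numbered 5 to 1455 for CHD8+/-, 0 to 5 for L834P/+ and 0 to 2 for R1242Q/+. Chd8 against WT changed by -0.70 to -0.40 for CHD8+/- day 8 and -0.55 to -0.48 for L1072F/+ day 14. Chd8 against CHD8+/- changed by 0.46 to 0.60 for R910Q/+ day 0 and R1242Q/+ day 0 and 0.31 to 0.45 for L1072F/+ day 0. The gene lists called against WT numbered 5 to 10 for CHD8+/- day 0, 3 to 9 for R910Q/+ day 0, 2 to 6 for R1242Q/+ day 0, 8 to 14 for L834P/+ day 8, 5 to 15 for R910Q/+ day 8, 6 to 23 for L834P/+ day 14 and 7 to 12 for R1242Q/+ day 14. The similarity r with CHD8+/- was 0.38 to 0.59 for L834P/+ day 0, 0.31 to 0.52 for R910Q/+ day 0, 0.094 to 0.51 for L1072F/+ day 0, 0.34 to 0.58 for R1242Q/+ day 0, 0.43 to 0.61 for L834P/+ day 8, 0.14 to 0.61 for R910Q/+ day 8, 0.12 to 0.83 for L1072F/+ day 8, 0.54 to 0.78 for R1242Q/+ day 8, 0.12 to 0.46 for L834P/+ day 14, 0.20 to 0.44 for R910Q/+ day 14, -0.44 to 0.72 for L1072F/+ day 14 and 0.19 to 0.49 for R1242Q/+ day 14. List medians of CHD8+/- against WT at day 14 that turned without CHD8+/- b ran from -1.30 to 0.15 for clustered protocadherins, -1.50 to 0.24 for REST-repressed neuronal genes and -1.60 to 0.22 for neuron.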

Other observations

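No test in this part was chosen after its result was seen. Some gene lists outside the comparisons described moved by the list test. Of the clustered protocadherins, 28 of 28 rose and 0 fell, over all genes and adjusted over the list alone (median 1.93, camera adjusted p = 1.9e-09, 0.467 with an estimated correlation) between days 8 and 14 in WT cells. In L1072F/+ cells at day 8, of the Notch targets and ligands, 0 of 15 rose and 14 fell over all genes, 0 and 15 adjusted over the list alone (median -1.47, camera adjusted p = 0.000772, 0.985 with an estimated correlation). In L834P/+ cells at day 0, of the glycolysis and hypoxia list, 0 of 27 rose and 0 fell, over all genes and adjusted over the list alone (median -0.19, camera adjusted p = 2.91e-05, 0.985 with an estimated correlation).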
